A study of Bos taurus with 8 samples.

How the data were processed

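RNA of bovine granulosa cells cultured with or without FSH was measured on 8 two-colour arrays, each with a control and a treated sample. Per the labels, the cells were filtered on a mesh of 104 µm, total RNA was amplified in 2 rounds of T7 transcription, and the product was coupled to Cy3 or Cy5 without an enzyme. The deposited scanner tables give the raw intensity of each spot at the wavelengths of both dyes, with its local background, and the authors applied neither background subtraction nor normalisation to these columns. The scanner software is not given in the sources used here. A deposited table of the whole series gives log2 ratios of the channels, centred near 0 by the authors in a way not stated. Under the same probe names its values did not follow the scanner tables: by name the correlation with the scanner ratios lay between -0.0119 and 0.0158 for each array. Sorted by size, the values correlated at 0.971 to 0.998, so their distributions were alike but not their assignment to probes. The series-wide ratios were therefore used for counts only, with no gene named from them. All gene names here rest on the probe names of the scanner tables.

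Each array held 45220 spots, of which 1426 were control spots and 43794 gene probes. Symbols came from the platform annotation, which lists 1 symbol for 21790 probes and more than 1 symbol for 0. The other 22004 probes have no symbol here and were tested without a name. Of the symbols, 20068 were current in RefSeq for cattle, 1644 were updated from a synonym and 78 were kept as given. No genome build is named with the probes, so no coordinates are printed. Median intensities were 1.27 to 1.38 times those of the negative control spots, so most probes lay near background and ratios of dim probes are compressed. At most 17 spots per array were saturated.

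The mean intensity over the pixels of a spot was corrected by its median local background with normexp and an offset of 50, and log2 ratios were normalised by loess within each array (limma 3.58.1 in R 4.3.3). Ratios were turned to FSH over control, and the arrays of opposite dye with the same replicate number were averaged, which gave 4 replicate means. Channel levels were taken after Aquantile scaling between arrays. A probe was tested if it exceeded the 95th percentile of the 153 negative control spots in at least 1 channel on at least 4 of 8 arrays. The mean ratio was tested against 0 with an intercept model and moderated variances (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Standard errors are those of limma. Dye terms were tested in the same way, over the 4 replicates. Tables were joined with Python 3.11.15 and figures drawn with matplotlib 3.10.9 and pandas 2.3.3.

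The pairing of arrays rests on the replicate numbers of the labels and on a series design with 4 control and 4 treated biological replicates in dye swap. The protocol text speaks of 8 biological replicates, which could be the 4 control and 4 treated ones together. The pairing was checked on the ratios: same-numbered arrays correlated across probes at r = 0.352 to 0.61, and arrays of different number and opposite orientation at -0.398 to 0.285. Arrays of different number and the same orientation lay at 0.143 to 0.715, so the check holds only among arrays of opposite orientation. In fits with the replicate as a random block, the correlation within replicates was 0.175 without and 0.72 with a dye term.

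Gene lists were tested with camera at a preset correlation of 0.01 on the brightest tested probe of each gene, with adjustment over the lists. Lists with fewer than 5 measured genes are given as values. The lists cover cAMP immediate-early genes, cAMP and MAPK feedback, steroidogenesis, cholesterol synthesis and uptake, granulosa identity and gonadotropin response, ovulation and cumulus expansion, extracellular matrix, TGF-beta, BMP and YAP targets, cell cycle, apoptosis and atresia, unfolded protein response, heat shock and oxidative stress, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, inflammation and interferon response. Markers of theca, endothelium, smooth muscle, fibroblast and stroma, immune cells, erythrocytes and oocytes were added. With an estimated correlation or for the directional test fry, the same lists were used. For blocked and separate-channel fits and for moderated variances with a trend, the lists were tested by cameraPR on the z-scores of the moderated statistics.

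Genes were named by a rule with 3 parts. The first takes the 10 named genes highest and the 10 lowest with FSH among probes past the threshold, filled up by the lowest unadjusted p. As no probe passed, all of these were filled in. The second takes a panel of 20 genes of granulosa cell function by their brightest probe, of which EREG was not analysed here. The third takes up to 4 genes of lowest p from each list. A further 15 genes in each direction, with the largest mean differences, were named after their values were seen. The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The use of the spot mean with the median background, the alternatives without replicate 3 in a blocked fit, with a term of its own for the control of replicate 3, with the spot median and with a background from negative spots were chosen after seeing the data.

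The steps were tested on simulated data with the spread of the FSH comparison over 36531 probes and 50 changed probes per size. At log2 changes of 0.5, 1, 2 and 4, the test over 4 replicate means recovered 32%, 78%, 86% and 96% of the changed probes, with 6 false calls in all. The changes were put on probes drawn at random, with the spread drawn separately for each probe. No replicate was simulated in which many changed genes fail to differ together, as they did in replicate 3. These shares therefore do not apply to genes such as NR4A1, with an SD between replicates of 1.94. Alternatives covered background correction, normalisation, the probe filter, the replicate unit, each orientation alone, the variance model, the threshold, probes per gene, the set test and leaving out each replicate.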

Results

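Granulosa cells, which line the ovarian follicle, make estradiol and carry the receptor for follicle-stimulating hormone (FSH), were compared after culture with and without FSH. The cells came from bovine follicles of 2 to 6 mm and were kept in culture for 48 h, and the treated cultures received FSH at 1 ng/ml during the last 4 h. Amplified RNA of a control and of a treated culture was hybridised together on each of 8 two-colour arrays. The arrays form 4 dye-swap pairs, numbered here as replicates 1 to 4 after the labels, with FSH in Cy5 on 4 arrays and in Cy3 on the other 4. Of 43794 gene probes, 36531 were tested, and 18810 of these stood for 13591 named genes. Between 71.4% and 84.2% of gene probes lay above the negative control spots in each array and channel. The number of arrays limits the precision. Nothing in the labels says that control and treated cultures of the same number came from the same ovaries, so p-values measure the spread between these samples.

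The comparison of FSH with control asks which transcripts differ after a short exposure to the hormone. The genes of this paragraph, which are among those with the largest mean differences, differed in replicates 1, 2 and 4 and far less in replicate 3. NR4A1, an immediate-early nuclear receptor, had a log2 ratio of FSH over control of 2.96 ± 0.77 (SE, n = 4 replicates), which is 7.76-fold. BAMBI, a pseudoreceptor that dampens TGF-beta signals, was at 2.88 ± 0.93. The other genes of this paragraph were chosen after their values were seen. PLK2, a polo-like kinase, was at 3.27 ± 0.98, GPAT3, an enzyme of triglyceride synthesis, at 3.13 ± 0.89, and ARHGAP18 at 2.58 ± 0.70. HAS2, the hyaluronan synthase of cumulus expansion, was at 2.51 ± 0.79 and ADAMTS1, a protease of the ovulatory follicle, at 2.45 ± 0.89. In the other direction TRIB2 was at -2.18 ± 0.65, STBD1, a glycogen-binding protein, at -1.98 ± 0.56, TOX2 at -1.81 ± 0.55, PRR15 at -1.78 ± 0.43 and PPARG, a nuclear receptor of lipid metabolism, at -1.38 ± 0.32. Other, dimmer probes of the same genes had the same sign but smaller ratios: 2.55 and 1.2 for GPAT3, 2.36 and 0.51 for BAMBI, and -1.23 and -0.22 for TRIB2.

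None of these values passed the test over the 4 replicate means. With limma, 0 of 36531 probes reached an adjusted p under 0.05, and the lowest adjusted p was 0.204. At an unadjusted p under 0.05 there were 4441 probes, 2521 higher and 1920 lower with FSH, where chance gives 1827. The log2 ratio had the same sign in all 4 replicates for 7433 probes, or 20.3%, where chance gives 12.5%. Ratios are correlated across probes, so counts can lie far from these chance values. With the signs of some replicates turned, 389 to 3756 probes reached an unadjusted p under 0.05 with limma. The call changed when the 8 arrays were fitted with the replicate number as a random block and a dye term: 1244 probes then passed, 729 higher and 515 lower. This fit counts arrays of the same RNA, with a single correlation within replicates for all probes. Where the spread lies mostly between replicates, its errors come out too small: 0.60 for NR4A1, against 0.77 over the replicate means. Calls of the blocked fit, here and below, are therefore weaker evidence than a test over 4 replicates. In that blocked fit NR4A1 (adjusted p = 0.0355), GPAT3 (adjusted p = 0.0398) and PLK2 (adjusted p = 0.0431) rose. PPARG (adjusted p = 0.0193), STBD1 (adjusted p = 0.0413), TRIB2 (adjusted p = 0.044) and TOX2 (adjusted p = 0.0491) fell in it. HAS2 (adjusted p = 0.0502), BAMBI (adjusted p = 0.056) and ADAMTS1 (adjusted p = 0.0779) did not pass.

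In replicate 3 these genes hardly differed between the channels, and the library labelled control stood near the level of the FSH libraries. The log2 ratio of NR4A1 was 3.22, 4.37, 0.13 and 4.10 in replicates 1 to 4. Its level in the control channel was 11.24, 10.91 and 11.00 (log2) in replicates 1, 2 and 4 and 14.88 in replicate 3, against 14.46, 15.28, 15.01 and 15.10 with FSH in replicates 1 to 4. TRIB2 stood at 12.82, 14.67 and 13.07 in the control channel of replicates 1, 2 and 4 and at 10.03 in that of replicate 3, against 11.01, 10.76, 9.96 and 10.16 with FSH. Over tested probes with a mean log2 intensity above 9, the ratios of replicates 1 and 2 correlated at r = 0.72, those of 1 and 4 at 0.43 and those of 2 and 4 at 0.65. Replicate 3 correlated with replicates 1, 2 and 4 at r = -0.10, -0.12 and 0.30. These correlations are across probes, which are not independent replicates.

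**Figure D1:**
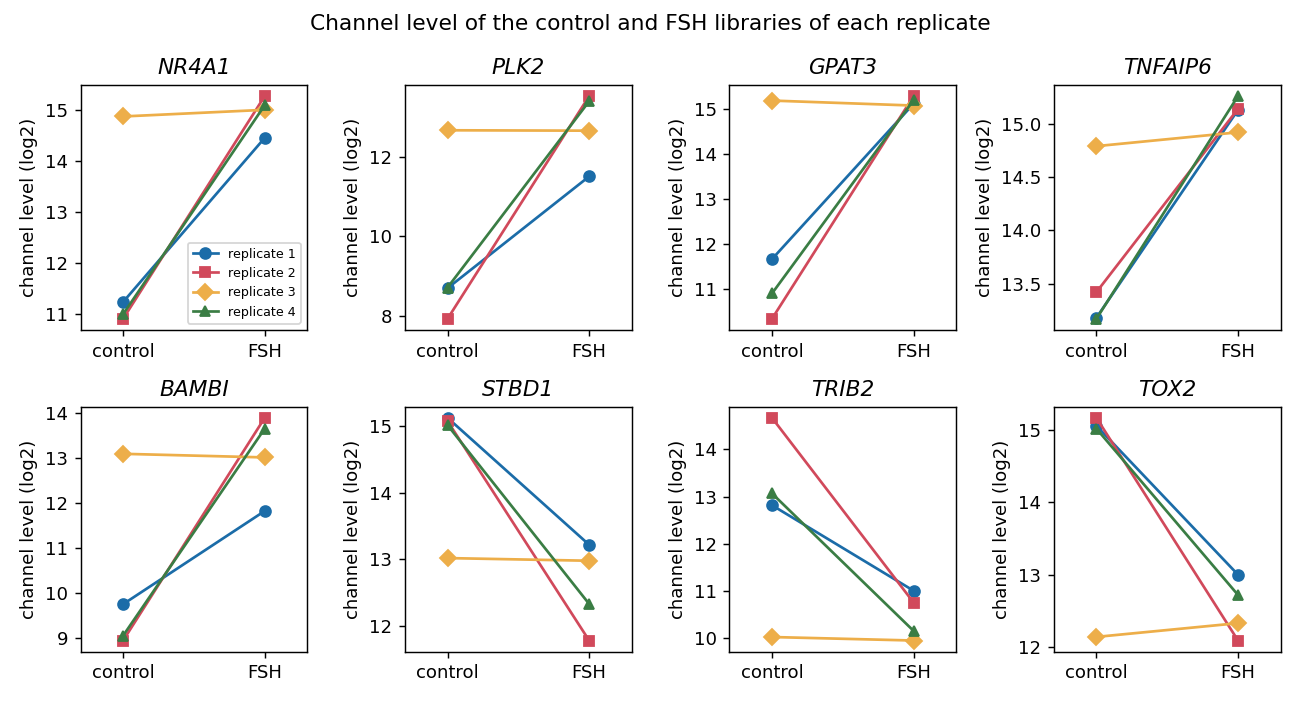
Level of 8 genes in the control and the FSH channel (vertical axis, log2 intensity after normalisation, mean of the pair of arrays of a replicate), with 1 line per replicate and vertical axes that differ between panels and do not start at 0. For NR4A1 the lines of replicates 1, 2 and 4 run from 11.24, 10.91 and 11.00 to 14.46, 15.28 and 15.10, while replicate 3 stands at 14.88 in the control and 15.01 in the FSH channel.

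Without replicate 3, an alternative chosen after seeing the data, 2610 probes passed in the blocked fit with a dye term, 1390 higher and 1220 lower with FSH. Of these, 1008 had also passed with all replicates. Replicate 3 was left out because the genes above hardly differed in it, so the smaller errors and lower p of this fit depend on the outcome itself and are no independent test, here and wherever a value without replicate 3 is given below. In this fit GPAT3 rose by a log2 ratio of 4.21 ± 0.25 (adjusted p = 0.00108), PLK2 by 4.37 ± 0.43 (adjusted p = 0.00391), NR4A1 by 3.90 ± 0.32 (adjusted p = 0.00247) and HAS2 by 3.43 ± 0.30 (adjusted p = 0.00306). PPARG was lower by a log2 ratio of -1.76 ± 0.11 (adjusted p = 0.00108), TOX2 of -2.48 ± 0.19 (adjusted p = 0.00221) and TRIB2 of -2.88 ± 0.33 (adjusted p = 0.00544). Over the 3 remaining replicate means alone, limma called 0 probes, with 5540 at an unadjusted p under 0.05.

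The named genes with the lowest unadjusted p differed by less but by similar amounts in all 4 replicates, replicate 3 included. Ranking by p over the same replicate means favours genes with a small spread between replicates. Similar ratios, a shared sign across arrays and a pass in the blocked fit thus follow largely from this choice and are no separate support. The 10 highest-ranked genes above control were FAM8A1, TMEM87A, C1H21orf62, TWIST2, ZNF345, UPK3A, ATXN7L3, NSG1, EPHB4 and GFER. Their log2 ratios lay between 0.61 ± 0.05 for FAM8A1 and 0.72 ± 0.06 for ZNF345, and each was above 0 in 8 of 8 arrays. The 10 below control were SNX5, CTCF, ZNF277, OARD1, TGFB1I1, NCAPD2, HMCES, JPT2, RABGAP1 and FASTKD1, between -0.62 ± 0.07 for OARD1 and -0.34 ± 0.04 for FASTKD1, each below 0 in 8 of 8 arrays. All had an adjusted p of 0.204 over the replicate means, and all passed in the blocked fit with a dye term, at adjusted p from 0.00831 for FAM8A1 to 0.0422 for FASTKD1. The probes of TMEM87A, TWIST2, ZNF345, UPK3A, ATXN7L3, NSG1, EPHB4 and GFER belong to a group of 132 bright probes, 68 of them with a symbol, that were higher with FSH in each replicate. Across the 4 controls the levels of this group followed a shared profile, with a median correlation of 0.933 between probes, so these are not 8 separate observations. A second probe of GFER (mean log2 intensity 11.6) was at 0.02 and one of TMEM87A (9.82) at 0.12. The other tested probes of these 20 genes were dim, where ratios are compressed, and are not compared.

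Among genes of steroid synthesis and follicle growth, the aromatase gene CYP19A1 was at a log2 ratio of 0.78 ± 0.20 and was higher in 8 of 8 arrays by its brightest probe. Its other probes, which were dimmer, were at 0.32 and 0.04, each below 0 in replicate 3. CYP11A1, which makes pregnenolone from cholesterol, was at 0.75 ± 0.34, and STAR, which carries cholesterol into mitochondria, at 0.49 ± 0.30 by its brightest probe. The other STAR probes, at 0.75 and 0.48, were above 0 in all 4 replicates, whereas the brightest was below 0 in replicate 3. FDX1, the electron donor of mitochondrial steroid enzymes, was at 0.48 ± 0.07 and higher in 8 of 8 arrays. HSD3B1 was at -0.77 ± 0.26 and the activin-binding protein FST at -0.76 ± 0.30. PTGS2, the inducible prostaglandin synthase, was at -1.06 ± 0.33. INHBB, an inhibin and activin subunit, was at 0.73 ± 0.13, and CCND2, a cyclin of granulosa cell growth, at 0.25 ± 0.06. The orphan receptor NR5A2 was at 0.69 ± 0.08 by its brightest probe, while a second bright probe was at -0.18 and a dim one at -0.10, and the brightest probe belongs to the group of 132 bright probes. In the blocked fit with a dye term CYP19A1 (adjusted p = 0.0309), FDX1 (adjusted p = 0.0323) and INHBB (adjusted p = 0.0131) rose and PTGS2 (adjusted p = 0.0494) fell. CYP11A1 (adjusted p = 0.155), STAR (adjusted p = 0.303), HSD3B1 (adjusted p = 0.0629), FST (adjusted p = 0.107) and CCND2 (adjusted p = 0.0878) did not pass.

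Leaving out replicate 3, in which CYP11A1, FST, HSD3B1 and ESR2 differed little or the other way, lowered their p by a choice that depends on the outcome. Without it in that fit, CYP11A1 was at 1.13 ± 0.17 (adjusted p = 0.0106), FST at -1.09 ± 0.16 (adjusted p = 0.0102) and HSD3B1 at -1.01 ± 0.17 (adjusted p = 0.0169). The brightest STAR probe was at 0.77 ± 0.20 (adjusted p = 0.0633). The estrogen receptor ESR2 was at -0.52 ± 0.09 (adjusted p = 0.019) in it, against -0.34 ± 0.16 over all replicate means. The FSH receptor FSHR was at -0.33 ± 0.08 (adjusted p = 0.0633) in it, against -0.12 ± 0.17 over all replicate means. The following values are means over all 4 replicates. FOXL2 was at -0.18 ± 0.09, AMH at -0.12 ± 0.09 and PDE4D at -0.05 ± 0.04. INHA was at 0.06 ± 0.07, AREG at 0.28 ± 0.11 and INHBA, which had 2 saturated values, at 0.24 ± 0.08. The luteinising hormone receptor LHCGR, at 0.00218 ± 0.04, lay above background in only 2 FSH and 2 control channels of the 8 arrays, so a difference was not detectable. IGF1 was at -0.002684 ± 0.04. FOXL2, PDE4D and IGF1 were nearly as dim, with mean log2 intensities of 6.92, 6.86 and 7, against 6.7 for LHCGR. Their small ratios therefore do not show that FSH had no effect.

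**Figure D2:**
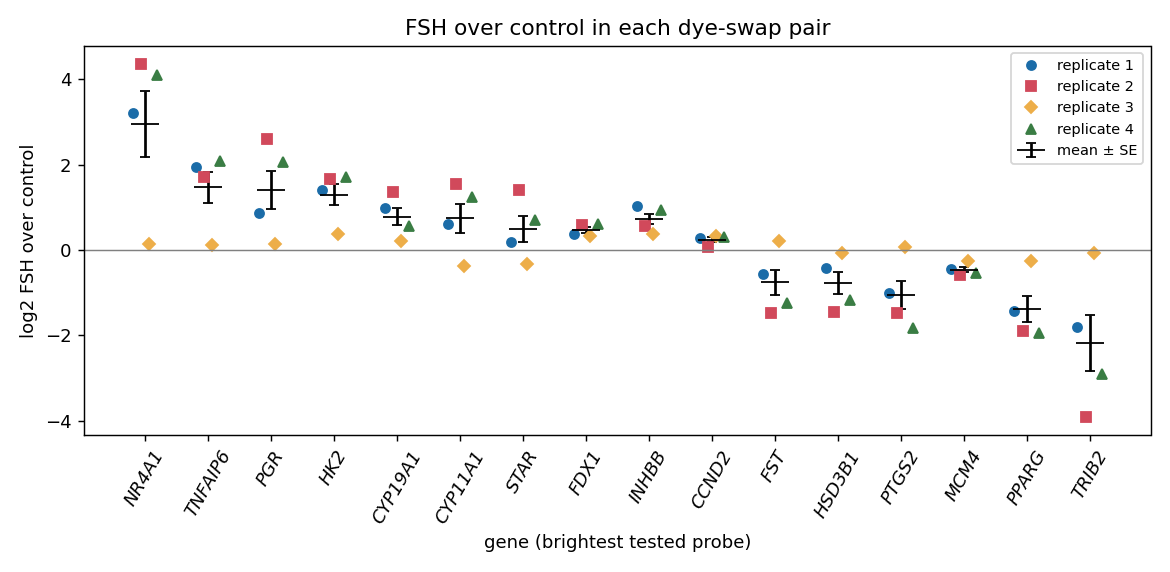
Log2 ratio of FSH over control (vertical axis) of 16 genes by the brightest probe, with 1 symbol per replicate and the mean ± SE over 4 replicates in black. Replicate 3 stands apart from the other replicates for NR4A1 (0.13) and TRIB2 (-0.07) but not for FDX1 (0.34), INHBB (0.38) and CCND2 (0.34).

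Of 24 gene lists fixed in advance, 4 were shifted at an adjusted p under 0.05 by camera with its preset correlation. None of the 4 calls held with an estimated correlation (adjusted p = 0.648 with an estimated correlation for each). No list member passed over all probes tested, so the members below are given by their values.

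The immediate-early genes of the cAMP response, the second messenger of the FSH receptor, were higher with FSH, with a median log2 ratio of 0.39 over 29 measured genes and 24 above 0 (adjusted p = 3.06e-05 by camera). NR4A1 was at 2.96, the transcription factor IER2 at 1.36 ± 0.41 by its brightest probe, the phosphatase DUSP1 at 0.39 ± 0.11 and KLF4 at 0.30 ± 0.09. A second, dim IER2 probe (mean log2 intensity 7.47) was at -0.108 and below 0 in all 4 replicates. The list median was 0.39, 1.06, -0.04 and 0.66 in replicates 1 to 4. Adjusted over the list alone, 0 members passed with limma, and 12 were higher at an unadjusted p under 0.05. In the blocked fit with a dye term 3 members rose and 0 fell, and without replicate 3 these counts were 13 and 1, with a list median of 0.83.

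The chaperones and regulators of the unfolded protein response were also higher, with a median of 0.17 over 23 genes and 19 above 0 (adjusted p = 0.00393 by camera). MANF was at 0.35 ± 0.07, the lectin chaperone CALR at 0.28 ± 0.07, SELENOS at 0.21 ± 0.05 and the ubiquitin ligase SYVN1 at 0.33 ± 0.09. The median was 0.19, 0.27, -0.09 and 0.23 in replicates 1 to 4. Adjusted over the list alone, 0 members passed with limma, and at an unadjusted p under 0.05 there were 7 higher and 1 lower. MANF (adjusted p = 0.0295) and SYVN1 (adjusted p = 0.0445) rose in the blocked fit. Without replicate 3, 6 members rose in that fit and 0 fell, with a list median of 0.25.

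Genes of ovulation and cumulus expansion were higher as a list, with a median of 0.10 over 28 genes and 20 above 0 (adjusted p = 0.0214 by camera). TNFAIP6, which crosslinks the hyaluronan matrix, was at 1.47 ± 0.36, the progesterone receptor PGR at 1.42 ± 0.44 and the neurotensin gene NTS at 0.62 ± 0.14. PTGS2, a member with a known role in ovulation, was lower. The median was 0.12, 0.22, -0.01 and 0.05 in replicates 1 to 4. Adjusted over the list alone, 0 members passed with limma, against 8 higher and 1 lower at an unadjusted p under 0.05. In the blocked fit TNFAIP6 (adjusted p = 0.0302), PGR (adjusted p = 0.0493) and NTS (adjusted p = 0.0274) rose.

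Cell cycle genes were lower with FSH, with a median of -0.10 over 37 genes and 28 below 0 (adjusted p = 0.0133 by camera). The replication helicase subunit MCM4 was at -0.46 ± 0.07, the checkpoint kinase BUB1 at -0.38 ± 0.10 and CDC20 at -0.27 ± 0.07, while CCND2 was above 0. The median was -0.09, -0.22, -0.05 and -0.29 in replicates 1 to 4. Adjusted over the list alone, 1 member passed. MCM4 (adjusted p = 0.0123) and BUB1 (adjusted p = 0.039) fell in the blocked fit. Without replicate 2 this call, that of the unfolded protein response and that of the ovulatory list ended, at adjusted p of 0.0775, 0.0501 and 0.137. Without replicate 4 the cell cycle call ended (adjusted p = 0.102), as did the ovulatory call without replicate 1 (adjusted p = 0.0738).

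Steroidogenesis genes had a median of 0.10 over 17 measured members (adjusted p = 0.138 by camera) and cholesterol genes a median of 0.12 over 28 (adjusted p = 0.0972). Targets of TGF-beta, BMP and YAP had a median of 0.10 (adjusted p = 0.131), with BAMBI above 0 and CCN1 at -0.79 ± 0.18. Some of these depended on replicate 3: without it the cholesterol list became a call (median 0.16, adjusted p = 0.011, and 0.0101 in the blocked fit). That list was also called with all replicates when the mean of all probes of a gene was used (adjusted p = 0.0102 by camera). Without replicate 3 the TGF-beta median went to 0.18 (adjusted p = 0.121, and 0.0466 in the blocked fit) and the steroidogenesis median to 0.04. Without it the medians of extracellular matrix and of heat shock genes were 0.13 and 0.11. Heat shock and oxidative stress genes were at 0.06 (adjusted p = 0.225), interferon genes at 0.04 (adjusted p = 0.222) and hypoxia and glycolysis genes at 0.02 (adjusted p = 0.389). In the last list HK2, a hexokinase, was at 1.3 ± 0.25 and rose in the blocked fit (adjusted p = 0.0127). Extracellular matrix genes were at 0.06 (adjusted p = 0.567), cAMP and MAPK feedback genes at 0.03 (adjusted p = 0.559), oxidative phosphorylation genes at 0.02 (adjusted p = 0.559) and granulosa identity genes at 0.00218 (adjusted p = 0.559). Cytosolic ribosomal proteins were at 0.00201 (adjusted p = 0.911), apoptosis genes at -0.04 (adjusted p = 0.899) and inflammation genes at -0.05 (adjusted p = 0.899).

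As lists, markers of other ovarian cell types showed no shift past the threshold. Immune markers had a median of 0.07 (adjusted p = 0.18), fibroblast and stroma markers of 0.03, theca markers of -0.00571, endothelium markers of -0.05 and smooth muscle markers of -0.06 (adjusted p = 0.559 for these 4). Oocyte markers were at 0.01 (adjusted p = 0.911), and the 4 measured erythrocyte markers at 0.01, without a test. In the blocked fit with a dye term, the immune marker TYROBP rose (log2 ratio 0.33, adjusted p = 0.0356) and ACTA2, held by the smooth muscle and theca lists, fell (-0.38, adjusted p = 0.0301), with no other call among these markers. Adjusted over the list alone, 6 members passed for granulosa identity, 2 each for steroidogenesis, theca and fibroblast, and 1 each for heat shock, smooth muscle and TGF-beta targets. For the remaining lists with no call this count was 0. Median and mean had opposite signs for apoptosis genes (-0.04 and 0.06), inflammation genes (-0.05 and 0.00233), endothelium markers (-0.05 and 0.01), oocyte markers (0.01 and -0.04), erythrocyte markers (0.01 and -0.04) and cytosolic ribosomal proteins (0.00201 and -0.00318). The test pointed up for apoptosis, oocyte and ribosomal genes and down for inflammation and endothelium genes.

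**Figure D3:**
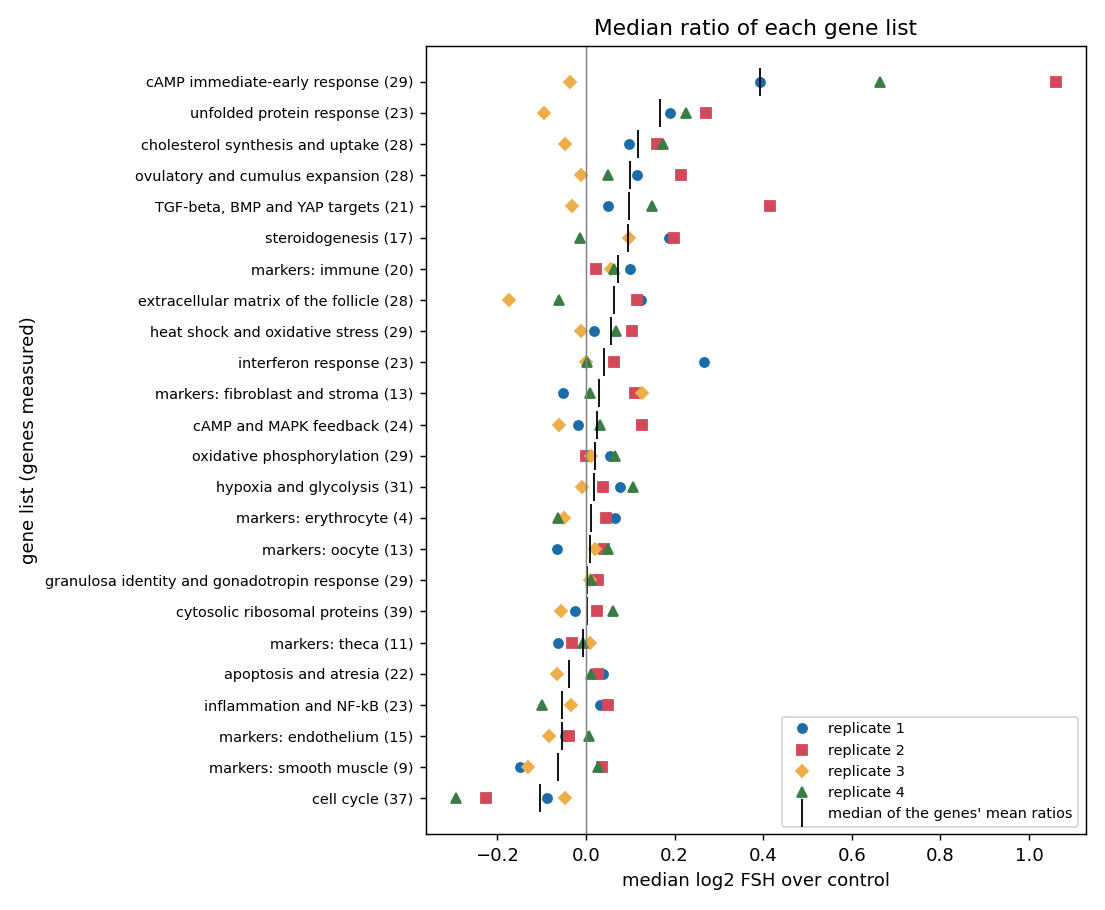
Median log2 ratio of FSH over control (horizontal axis) of 24 gene lists, with the number of measured genes in brackets, 1 symbol per replicate and a bar for the median of the genes' mean ratios. The cAMP immediate-early list is at 0.39, 1.06 and 0.66 in replicates 1, 2 and 4 and at -0.04 in replicate 3, and the cell cycle list is below 0 in all 4 replicates.

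The comparison of dye orientations shows how far a ratio from a single orientation reflects the dye or the slide, which carry the same orientation and cannot be told apart. With limma, 21492 of 36531 probes differed between orientations at an adjusted p under 0.05, 11955 in one direction and 9537 in the other. The median absolute dye term was 0.10 (log2), against 0.07 for the mean FSH ratio, while the 95th percentiles were 0.33 and 0.43. The dye term cancels in the mean of a dye-swap pair, from which the replicate ratios were taken.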

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

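The tests of the control of replicate 3 and of the bright probes below were chosen after the result was seen, whereas the sign turns of the replicates were planned. Among the 153 named genes, 459 sets of 4 values (control levels, FSH levels and log2 ratios) were examined for a value far from the other replicates. Such a value was found in 28 sets, or 6.1%, where chance gives about 5%. Of these, 18 were control levels, and 14 of the 18 lay in replicate 3. Over all tested probes 6.06% of control levels stood apart, 796 of 2214 in replicate 3.

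In the control of replicate 3 the following stood above the other controls (log2 level): NR4A1 at 14.9, TNFAIP6 at 14.8, PLK2 at 12.7, CALR at 12.4, ARHGAP18 at 11.7, AKAP7 at 11, FGF2 at 10.1, GRK5 at 9.67, TAP1 at 9.02 and NOG at 7.7. The genes STBD1 at 13, TOX2 at 12.1 and PRR15 at 8.56 stood below the other controls there, and RPL6 at 14.7 stood apart as well. In the control of replicate 1 BTG4 stood apart at 8.95, COL1A1 at 7.86 and SLC4A1 at 7.2, and in that of replicate 4 PDE4B at 10.9. FSH levels stood apart in replicate 1 for PTGS2 at 9.03, SREBF1 at 11.2 and TGFB1I1 at 8.35, and in replicate 4 for TIMP2 at 14.4. Log2 ratios stood apart in replicate 1 for BTG4 at -1.96 and ISG15 at 1.87, and in replicate 2 for IGF1R at 1.23. In replicate 3 they did so for CCN1 at -0.111, FSHR at 0.513 and IGF1 at 0.0583. The number of probes whose ratio differed between dye orientations, 21492, is a difference between the groups of arrays.

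The first pattern is that the library labelled control of replicate 3 lay at the level of the FSH libraries, over 123 probes that differed more than 2-fold in the same direction in replicates 1, 2 and 4, on a scale from 0 for the controls to 1 for the FSH libraries of these replicates. The FSH library of replicate 3 lay at 0.982, which argues against an exchange of the RNAs of this replicate, since its partner was not out of place. The control library lay at 1.04, at 1.02 over the 100 probes higher and 1.17 over the 23 probes lower with FSH, on both of its arrays, which is consistent, for these probes, with RNA of FSH-exposed cells in its place. Among bright probes by their smallest difference in replicates 1, 2 and 4, the 60 higher by 0.7 to 1 and the 77 higher by more than 1 had medians of -0.04 and -0.08 in replicate 3, while the 332 higher by 0.4 to 0.7 had 0.22, but 125 of these belong to the group below, which was chosen for being higher in replicate 3 as well. Untreated cells that were already active could give the same position (1.17 over the probes lower with FSH), and the position does not separate them from FSH-exposed RNA. It describes these 123 probes only, which were chosen for large differences in the other replicates. Over all bright probes the ratios of the arrays of replicate 3 correlated at r = 0.574, against 0.611 for those of replicate 1. The RNAs of replicate 3 thus differed from each other reproducibly elsewhere.

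The next pattern is a group of 132 bright probes, 68 of them with a symbol, that were higher with FSH by a log2 ratio over 0.4 in each replicate, replicate 3 included, with a median of 0.71, while 19 bright probes were lower than -0.4 in each replicate. The group holds the probes of TMEM87A, TWIST2, ZNF345, UPK3A, ATXN7L3, NSG1, EPHB4, GFER, NR5A2 and SRXN1. It was not uniform: SRXN1 was at 0.955, 2.98, 0.505 and 2.22 in replicates 1 to 4, against group medians of 0.61, 0.53, 0.66 and 1. The probes of ELL2, NDP and STK17A were likewise highest in replicate 2 and lowest in replicate 3. The limit of 0.4 was lowered from a higher one that left too few probes to test, and the rule for reading the test was changed after its values were seen. Across the 4 controls the probes of the group shared a profile, with a median correlation of 0.933, against at most 0.0857 in 100 random draws of as many bright probes. Other probes of the same genes had a median of 0.02 over 50 probes, many of them dim. Over the 16 bright ones the median was 0.157, with quartiles of -0.04 and 0.79 on either side of 0.36, which is 50% of the group's median, so signal from RNA other than the named genes and a response of the named genes may each be at work and cannot be told apart.

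With 4 replicates there are 8 ways to turn the signs of the replicate ratios, too few for a share under 0.05. The number of probes at an adjusted p under 0.05 was 0 in all 8, with 0 as the highest of the others. At an unadjusted p under 0.05 the real signs gave 4441 and the highest other 3756, with replicate 3 turned, so 1 of 8 gave as many. The number of lists was 4 with the real signs and 4 as the highest other, again with replicate 3 turned, so 2 of 8 gave as many. For dye orientation the real signs gave 21492 probes and the highest other 0, so 1 of 8 gave as many.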

How the results depend on the processing

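The alternatives without replicate 3 in a blocked fit, with a term of its own for the control of replicate 3, with the spot median and with a background from the negative spots were chosen after seeing the data; the others were planned. Aquantile scaling after loess leaves log2 ratios unchanged, so its equal result is in the counts below but tests nothing for ratios. The count of 0 probes for FSH against control with limma (4441 at an unadjusted p under 0.05) moved to 1426 with a replicate block, 1244 with block and dye term, 1848 with no block, 2818 with no block and a dye term, 4325 with separate channels, 1975 with only the arrays with FSH in Cy5 and 409 with only those with FSH in Cy3. It moved to 724 at an unadjusted p under 0.05 and at least 1.5-fold, to 2610 for the 6 arrays left after replicate 3 with block and dye term, and to 6975 when the control of replicate 3 had its own term. Fits without a block and the separate-channel fits treat arrays of the same RNA as independent. The blocked fits share a correlation within replicates across all probes. The separate-channel fits share a correlation within spots, which was -0.242 without the own term. Within a single orientation FSH and dye change together, and 21492 of 36531 probes had a dye term at an adjusted p under 0.05 with limma. The counts from a single orientation therefore cannot be read as an effect of FSH. Beyond this the cause was not tested. The count was 0 under the other alternatives, series-wide ratios included, and 0 to 0 without each replicate.

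The count of 4441 moved to 6672 and 8474 with no block, without and with a dye term, to 6736 for the 6 arrays, 8412 with separate channels, 10245 with the own term, 11082 and 10418 with only FSH in Cy5 and Cy3, and 2586 with a variance trend. It was 1969 with the mean of all probes of a gene, where fewer values were tested, and 2777 to 5540 without each replicate, lowest without replicate 2. The 4 shifted lists became 6 with median centring, 6 for the 6 arrays with block and dye term, 5 with the own term and 5 with the mean of all probes of a gene. They became 1 with only FSH in Cy3, 0 with an estimated correlation and 0 with fry, and were 1 to 5 without each replicate, most without replicate 3; the cause was not tested. Of 25 alternatives the cAMP immediate-early list was called in 23 (adjusted p 1.83e-09 to 0.648), the unfolded protein response in 21 (5.89e-05 to 0.648), and cell cycle (0.00265 to 0.648) and ovulatory genes (0.00402 to 0.648) in 20 each. Cholesterol genes were called in 4, and TGF-beta targets, ribosomal proteins and heat shock genes in 1 each. All of these calls used the preset correlation of 0.01, so their number is no separate support. The estimated correlation was 0.365 for the cAMP immediate-early list and 0.201 for the unfolded protein response. It was 0.166 for cell cycle and 0.148 for ovulatory genes. The dye count was 18011 to 20239 without each replicate, 21034 with median centring and 21687 without background correction.

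Of 3500 values of the 153 named genes, 707 passed the threshold in the same direction and 0 in the opposite one, 103 moved by more than the spread between replicates and 2690 did not. All 707 came from fits with or without a block, separate channels and single orientations. The other alternatives had no call. Those fits reuse the same RNA or cannot separate FSH from dye, and many of the genes were chosen by p or size in the same data. The passes and their shared direction are thus no separate support. The sign held for 131 genes and turned in 36 values of the rest, FSHR, AMH, INHA, INHBA, CDC20 and SREBF2 among them. The series-wide table of ratios could not be used for lists and named genes, as its values did not follow the scanner ratios under the same probe names. Signal over background limits dim probes such as LHCGR.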

Other observations

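Apart from the values without replicate 3, no test of this part was chosen after the result was seen, but BMP2 and IGFBP3 were named after their values were seen. PSMB9, a subunit of the immunoproteasome, had a log2 ratio of 0.83 ± 0.20 (SE, n = 4 replicates) and was higher in 8 of 8 arrays, and TAP1, the peptide transporter, was at 0.71 ± 0.27. NFKB1 was at 0.77 ± 0.21. In the blocked fit with a dye term, PSMB9 (adjusted p = 0.0255) and NFKB1 (adjusted p = 0.0377) passed and TAP1 (adjusted p = 0.0946) did not, by limma. The lists that hold these genes were not shifted, at adjusted p of 0.222 for interferon and 0.899 for inflammation genes. Among genes of growth factor signalling, IGF1R, the receptor of insulin-like growth factor 1, was at 0.74 ± 0.14 and rose in the blocked fit with a dye term (adjusted p = 0.0134 by limma), while FOXO1, a transcription factor held back by insulin signalling, was at -0.62 ± 0.12 and fell in it (adjusted p = 0.0143). The transcription factor GATA4, at -0.59 ± 0.13 and lower in 8 of 8 arrays, did not pass (adjusted p = 0.0595). The antioxidant gene SRXN1 was at 1.66 ± 0.45 and higher in all 4 replicates, at 0.95, 2.98, 0.50 and 2.22. Its probe met the limit of the bright group, whose source as a set was left open. The control levels of this probe were 12.12, 10.25, 13.11 and 10.96 in replicates 1 to 4. They did not follow the group's medians of 10.9, 10.4, 11.7 and 12.5. The other SRXN1 probe, a dim one, was at 0.42 and above 0 in all 4 replicates. BMP2 was at 1.79 ± 0.71, the glucose transporter SLC2A1 at 0.59 ± 0.18 and IGFBP3 at 1.88 ± 0.46. In the blocked fit IGFBP3 rose (adjusted p = 0.0241), while BMP2 (adjusted p = 0.0997) and SLC2A1 (adjusted p = 0.0573) did not pass. Replicate 3 decided this, and the same for TAP1: without it, a choice that depends on the outcome, BMP2 was at 2.40 ± 0.49 or 5.27-fold (adjusted p = 0.0299), SLC2A1 at 0.76 ± 0.13 (adjusted p = 0.0164) and TAP1 at 1.03 ± 0.11 (adjusted p = 0.005) in the blocked fit by limma.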
